A study of Mus musculus with 12 samples.

How the data were processed

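RNA of 12 pooled tissue samples, 3 each of CP tumor and wild-type CP at P0 and at P21, was hybridized to Illumina mouse BeadChips that carry 45281 probes. Per the labels' protocols, RNA was extracted with Trizol, cleaned on PureLink columns with DNase I, checked on a Bioanalyser and made into biotin-labelled cRNA with the Ambion MessageAmp kit. Per the labels, each sample pooled tissue of several animals of one genotype, and 3 separate sets were collected per group. How many animals each pool held, their sex and their litters are not given in the sources used here, so p-values measure the spread between these samples, which may be partly technical.

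Per the file headers, the deposited scanner table gives for each array an average bead signal (an intensity on a linear scale, not normalized) and a detection p-value for each probe. The software that made these values is not given in the sources used here. A second table deposited by the authors holds one normalized intensity per probe and array. Its columns kept the rank order of the scanner values of their own array (Spearman 1, and at most 0.936 with any other array), its scale was linear, and its column medians lay between 153.0 and 153.1. The normalization method behind it is not given in the sources used here, and it was used only as an alternative. All array columns were mapped to samples through the labels.

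Median raw signals were 134 to 179.9, and 19043 to 23632 probes per array had a detection p-value under 0.05. Spearman correlations of raw signals between arrays of a group were 0.874 to 0.936. The number of arrays, 3 per group, limits the precision.

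Background was corrected with the normexp method of limma 3.58.1 in R 4.3.3, with negative control levels inferred from the detection p-values (936 control values per array), an offset of 16, quantile normalization over the 12 arrays and a log2 transform. A probe was kept where its detection p-value was under 0.05 on at least 3 arrays (24000 probes) and it had one gene symbol (20021). GEO's platform annotation gave one symbol for 34885 probes and several for 18, and did not list 10378. Symbols were updated through Entrez IDs for 34807 probes and accessions for 11 with a RefSeq gene table of assembly GRCm38.p6, used for names only, and 67 kept the annotation's symbol. The build behind the array is not given in the sources used here, and no coordinates are printed. A gene was represented by its brightest probe, and 5066 of 12379 genes had more than one probe. Probes of one gene passed in opposite directions for 0 genes at P0, 3 at P21, 0 in the interaction, 11 with age in wild-type CP and 6 with age in tumors. Gli1, Mycn, Atoh1, Ccdc78, Cdc20b and Lfng did not pass the filter, and Mki67 had no probe with that name.

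One mean per group was fitted over all 12 arrays with limma (lmFit and eBayes, residual degrees of freedom 8, prior degrees of freedom 4.21), with Benjamini-Hochberg adjustment over all genes within a comparison and a threshold of 0.05. The comparisons were tumor against wild-type CP at each age, the difference of these effects (interaction), and P21 against P0 within each genotype. Each SE comes from the spread pooled over all 12 arrays, so a gene has the same SE at P0 and at P21. Overlap was tested with Fisher's exact test per direction, 2-sided. The 27 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated for each list, for lists with at least 3 genes tested. Where a gene was below background on every array of a group, the difference is given as a lower bound, the other group's mean over the higher of the probe's own signal and the lowest detected signal of each array.

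The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes 18 fixed genes (Notch1, Hes1, Hes5, Hey1, Gli1, Ptch1, Shh, Mycn, Gmnc, Mcidas, Foxj1, Ccno, Ttr, Aqp1, Otx2, Lmx1a, Mki67 and Atoh1), the 8 largest rises and 8 largest falls with non-overlapping groups in each tumor comparison, up to 4 passing members of each list, and 6 in each direction for the other comparisons. Lists of mast cells, melanocytes, neutrophils, reactive astrocytes, ribosomal proteins and oxidative phosphorylation were added after the data were seen.

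Tumor and wild-type samples share replicate numbers in the labels. At P0 samples of the same number deviated together from their group means for numbers 1 and 2 (r = 0.43 and 0.43). For number 3 r was 0.104, close to 0.097 for tumor 2 with wild-type 3 and 0.088 for tumor 3 with wild-type 1. By the data alone a P0 pairing thus appears for numbers 1 and 2 and is not settled for number 3. Every P0 value outside the block alternative comes from a fit without pairs. At P21 samples of the same number did not deviate together (r = -0.08, -0.03 and -0.14). The fit with the number as a block was an alternative at both ages.

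The calculation was tested on simulated arrays with 200 of 12379 genes changed. For log2 changes of 0.5, 1 and 2 it recovered 2.99%, 32.8% and 95.5% of changed genes at P0 with 2 false calls, 1.49%, 38.8% and 100% at P21 with 5 false calls, and 0%, 4.48% and 72.7% for the interaction with 3 false calls. All 20 simulated lists shifted by 1 log2 unit were called, and 1 of 20 unshifted lists was. The simulated genes varied independently, whereas estimated correlations in the data were 0.252 for mitosis genes, 0.454 for astrocytes and 0.764 for neurons. The simulation therefore gives no error rate for lists of correlated genes. Each simulated gene also had the same spread at P0 and at P21. The recovered percentages are thus not separate rates for each age, and a spread that differs between the ages was not tested. The simulation changed 200 genes, whereas 1397 genes passed at P0 and 2221 at P21 in the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

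The alternatives were an offset of 50, no background correction, cyclic loess, median scaling, quantile normalization within each BeadChip, the authors' normalized values, no filter, a detection p-value under 0.01, probes detected on all 12 arrays, the mean of a gene's probes, only the 6 arrays of a comparison, the replicate block, array weights, an estimated correlation and leaving out each array in turn. The mean level of ribosomal protein and oxidative phosphorylation genes as a covariate was added after the data were seen. Probes without a gene name were left out of the main tests, and control probes are not analysed here.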

Results

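Gene expression was measured in tumors of the choroid plexus (CP), the secretory epithelium of the brain ventricles that produces cerebrospinal fluid. The tumors came from the hindbrain CP of Math1-cre;Rosa26-NICD1 mice, in which Cre recombinase driven by Math1 (also called Atoh1) switches on the active intracellular domain of the Notch1 receptor. Wild-type CP served as control, and both tissues were taken at the day of birth (P0) and at postnatal day 21 (P21), with 3 arrays in each of the 4 groups. Each sample was tissue pooled from several C57BL/6 animals of one genotype. The series title names the questions behind the design, which are whether Notch signaling holds back the differentiation of multiciliated cells, whether the tumors start from progenitors, and how they respond to Sonic hedgehog (Shh) made by the epithelium. Between 19043 and 23632 of 45281 probes were detected per array, the median raw signal was 134 to 179.9, and 12379 named genes were tested. All P0 arrays lay on one BeadChip and all P21 arrays on the other, so age and BeadChip cannot be told apart. Tumor and wild-type CP were compared within a BeadChip. Per the file headers, tumors were arrays A to C and wild-type CP arrays D to F on both BeadChips. Array position therefore cannot be told apart from genotype. Median raw signals were 160.7 to 179.9 in tumors and 144.2 to 153.9 in wild-type CP at P0. At P21 they were 154.9 to 156.4 and 134 to 141.2.

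Age and genotype parted the 12 arrays along the first principal components. P0 arrays lay between -52.0 and -23.9 on the first component (35.3% of the variance) and P21 arrays between 23.7 and 46.6. Tumor arrays lay between 14.3 and 57.1 on the second component (26.9%), and wild-type arrays between -44.0 and -16.8. The mean correlation with the other arrays of the group was 0.946 for P0 wild-type sample 1 and 0.949 for P21 tumor sample 1, against 0.990 for each P21 wild-type sample.

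**Figure D1:**
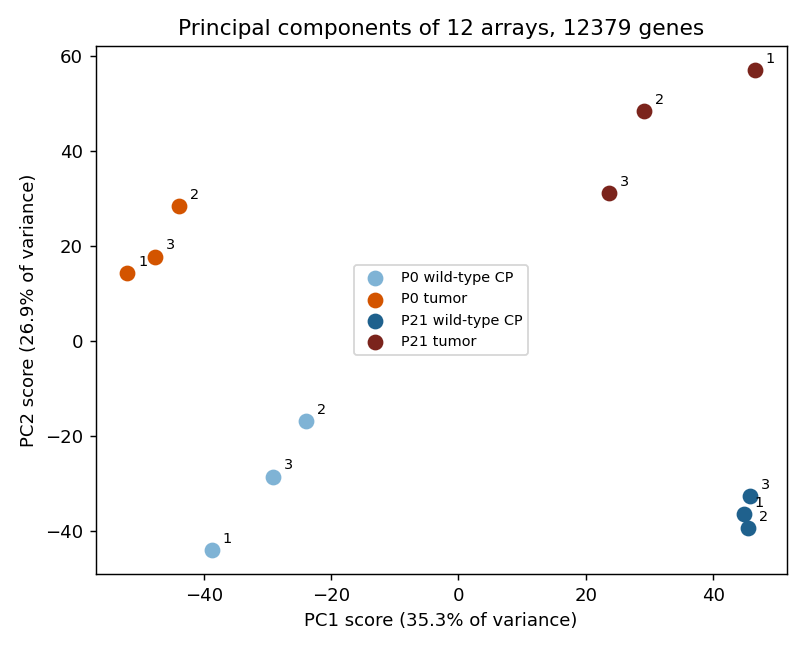
Scores of the 12 arrays (points, numbered by replicate and colored by group, n = 3 per group) on the first 2 principal components of the normalized log2 intensities, with the percent of variance on each axis label. The first axis (35.3%) parts P0 from P21 and the second (26.9%) parts tumors, at 14.3 to 57.1, from wild-type CP, at -44.0 to -16.8.

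The Notch1 transcript, whose intracellular part the transgene encodes, was higher in tumors at both ages. The rise was 1.14 ± 0.25 log2 units at P0 (SE, n = 3 per group, limma adjusted p = 0.0116) and 2.12 ± 0.25 at P21 (adjusted p = 8.33e-05). In the text, each SE rests on the spread pooled over the arrays of all groups, not on the arrays compared alone. Where the Notch1 probe lies relative to the transgenic fragment is not given in the sources used here, so this rise does not check the genotype labels.

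The P0 comparison asked what distinguished newborn tumors from CP of the same age. Direct Notch target genes rose, among them Nrarp, a feedback inhibitor of Notch signaling (3.87 ± 0.27 log2, SE, adjusted p = 4.32e-06), and the transcriptional repressor Hey1 (2.36 ± 0.24, 7.26e-05). Genes of the cell division cycle rose together, such as the replication helicase subunit Mcm5 (3.30 ± 0.23, 4.19e-06) and the DNA topoisomerase Top2a (3.07 ± 0.41, 0.00053). The Wnt ligand gene Wnt3a was 29.8-fold higher (4.90 ± 0.21, 1.98e-07). Members of the ciliary and CP epithelial lists that passed the test were mostly lower. In all, 1397 genes passed an adjusted p of 0.05 in limma, 619 higher and 778 lower in tumors, and 443 and 413 of these differed by at least 1 log2 unit. The 2 groups did not overlap for 24.8% of genes, against 10% by chance. For 108 of the passing genes one group was below background on all its arrays. The count was 730 without P0 tumor sample 3 and 561 (326 higher, 235 lower) when only the 6 P0 arrays were fitted. It was 2519 with the level of ribosomal and oxidative phosphorylation genes as a covariate, chosen after the data were seen. P0 SEs and p-values rest on the spread pooled over all groups. Since fewer genes passed with the P0 arrays alone, these SEs and p-values may be too small for P0.

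Of 9 Notch target genes tested at P0, 6 rose and none fell, and 6 rose and 1 fell when adjusted over the list alone (the latter Hey2, -0.66 ± 0.23, chosen after its values were seen). The list median was 2.06 log2 (camera adjusted p = 1.32e-06, and adjusted p = 0.0287 with an estimated correlation). Mixed groupings of the arrays gave up to 8 shifted lists at P0 against the real 9, and up to 13 at P21 against 12. Camera p-values at the preset correlation may therefore be too small, here and below. The repressor Hes5 was below background in all wild-type arrays and at least 10.3-fold higher in tumors (adjusted p = 0.000166). Notch3, a Notch receptor, rose by 2.46 ± 0.35 (0.00077) and Hes1 by 1.53 ± 0.27 (0.00345). Of 12 receptors, ligands and cofactors of the pathway, Notch1 was the only one to pass, over all genes or adjusted over the list alone, and the list did not shift (median -0.16 and mean 0.02, camera adjusted p = 0.965).

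Of 7 Wnt target genes, 6 rose and none fell at P0, with the same counts adjusted over the list alone (median 1.82, camera adjusted p = 3.95e-08, and adjusted p = 0.00744 with an estimated correlation). These included Axin2, a feedback inhibitor of Wnt signaling (1.82 ± 0.22, 0.000233), Nkd2 (2.32 ± 0.22, 4.09e-05), the transcription factor gene Sp5 (1.91 ± 0.22, 0.000166) and the R-spondin receptor Lgr5, at least 3.86-fold higher (adjusted p = 0.000471). In the list of CP and roof plate factors, 3 of 15 members rose, Wnt3a and the Wnt agonists Rspo1 (3.53 ± 0.39, 0.000135, detected on 1 of 3 wild-type arrays) and Rspo2 (at least 2.49-fold, adjusted p = 1.56e-05). Adjusted over the list alone, 3 rose and 1 fell (Bmp6, -0.65 ± 0.22, chosen after its values were seen). That list's shift (median 0.13, mean 0.72, camera adjusted p = 0.0203) was lost with an estimated correlation (adjusted p = 0.207 with an estimated correlation). It was also lost without tumor sample 1, 2 or 3 (0.201, 0.126, 0.067), without wild-type sample 2 or 3 (0.0555, 0.0696), with the replicate number as a block (0.0549), with median scaling (0.067) and with probes detected on all 12 arrays (0.979). The CP transcription factor genes Otx2 (-0.03 ± 0.26, 0.958) and Lmx1a (0.43 ± 0.20, 0.207) did not pass.

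Of 15 mitosis genes, 14 rose and none fell at P0, also when adjusted over the list alone (median 1.91, camera adjusted p = 1.03e-19, and adjusted p = 0.0137 with an estimated correlation). Besides Top2a these included the mitotic kinase Aurkb (2.70 ± 0.29, 0.000128) and the spindle motor Kif11 (2.42 ± 0.23, 5.07e-05). Of 19 DNA replication genes, 17 rose and none fell (median 1.73, camera adjusted p = 1.92e-20, and adjusted p = 0.00744 with an estimated correlation), and 18 rose and 1 fell adjusted over the list alone. The one that fell was Pcna (-0.71 ± 0.21, chosen after its values were seen), the sliding clamp of DNA polymerase. Thymidine kinase Tk1 rose by 3.22 ± 0.40 (0.000306) and Uhrf1, which maintains DNA methylation during replication, by 2.30 ± 0.20 (2.72e-05). Among 7 CDK inhibitors, Cdkn2c rose (1.63 ± 0.27, 0.00257), Cdkn2b joined it adjusted over the list alone (0.90 ± 0.28, chosen after its values were seen), none fell, and the list did not shift (median -0.05, mean 0.32, camera adjusted p = 0.401). Mki67 had no probe with its name.

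Of 11 regulators of multiciliated cells, 3 fell and none rose at P0. Ccno, needed to multiply centrioles, fell by 1.06 ± 0.21 (0.00637). Mcidas, which starts the multiciliated program, fell by 0.87 ± 0.24 (0.0367). Trp73, at least 1.86-fold lower, was below background in all tumor arrays (adjusted p = 0.0161). The Mcidas call ended without tumor sample 3 (0.149) or wild-type sample 1 or 3 (0.111, 0.0993), with no background correction (0.0558), cyclic loess (0.0539), median scaling (0.0739), the authors' values (0.0536) or only the 6 P0 arrays fitted (0.164), and that of Trp73 without tumor sample 1 or 3 (0.0566, 0.0554) or wild-type sample 3 (0.0604). Foxj1, the master regulator of motile cilia, differed by -0.39 ± 0.29 (0.436), and Gmnc, which acts upstream of Mcidas, by -0.43 ± 0.40 (0.553). Without wild-type sample 1, where Gmnc was not detected, its difference was -1.04 and passed (0.0218). Adjusted over the list alone 4 fell, with Deup1 as the added one (-0.65 ± 0.23, chosen after its values were seen). The list shifted down (median -0.39, camera adjusted p = 0.042), but adjusted p = 0.126 with an estimated correlation. The shift also ended without tumor sample 1 or 3 (0.0864, 0.081), without wild-type sample 2 or 3 (0.0555, 0.129), with the replicate block (0.056), median scaling (0.0619), the mean of probes (0.069), probes detected on all 12 arrays (0.211) and the covariate (0.0826).

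Of 39 components of motile cilia, 11 fell and 1 rose at P0, and 14 fell and 1 rose adjusted over the list alone (median -0.54, camera adjusted p = 5.72e-05, but adjusted p = 0.158 with an estimated correlation). The dynein assembly factor Lrrc6 fell by 1.30 ± 0.21 (0.0018), Cfap53 by 1.13 ± 0.20 (0.00355) and the axonemal tektin Tekt1 by 1.13 ± 0.19 (0.00242). The one that rose was Tppp3, a microtubule-binding protein (1.14 ± 0.31, 0.0343), which no longer passed without tumor sample 1 or 3 (0.123, 0.131) or wild-type sample 1 or 2 (0.0798, 0.0822), nor with only the 6 P0 arrays fitted (0.104). Among 23 genes of intraflagellar transport and the primary cilium, 3 fell and none rose, also when adjusted over the list alone. Ift57 was at least 2.31-fold lower (adjusted p = 0.00786), but with the mean of its probes it was -0.54 and did not pass (0.0862). Bbs5 (-0.86 ± 0.22, 0.0248) lost its call without tumor sample 1 or 2 (0.0859, 0.0548) or wild-type sample 3 (0.0878) and with only the 6 arrays (0.134). Bbs4 (-0.61 ± 0.17, 0.035) lost its call without tumor sample 1 or 3 (0.086, 0.115), without wild-type sample 1 (0.0928), with the block (0.0642) and with only the 6 arrays (0.204). The list did not shift (median -0.30, camera adjusted p = 0.0791), but it did without tumor sample 2 (0.0232) or wild-type sample 1 (0.00937) and with no detection filter (0.0263).

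Of 31 CP epithelial genes, 10 fell and none rose at P0, and 12 fell adjusted over the list alone (median -0.50, camera adjusted p = 7.7e-05, but adjusted p = 0.126 with an estimated correlation). The angiotensin-converting enzyme Ace fell by 1.13 ± 0.24 (0.0111), the cation channel Trpv4 by 1.11 ± 0.21 (0.00531) and the water channel Aqp1 by 1.13 ± 0.29 (0.0248). The Ace call ended without tumor sample 3 (0.0563), and the Aqp1 call without tumor sample 1 or 3 (0.0905, 0.0883) or wild-type sample 2 or 3 (0.07, 0.0715). With only the 6 P0 arrays fitted none of these 3 passed (Ace 0.0507, Trpv4 0.052, Aqp1 0.11), and with the mean of probes Ace was -0.34 (0.771) and Trpv4 -0.25 (0.856). Transthyretin, Ttr, which CP secretes in large amounts, did not pass (-0.04 ± 0.15, 0.902), but its signal lay near the top of the scale, where a difference can be hidden.

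Hedgehog pathway genes moved in both directions at P0. Shh itself fell by 1.39 ± 0.29 (0.00891), and Hhip, a target gene that encodes a decoy receptor for the ligand, by 1.43 ± 0.31 (0.0121). Ccnd1, a cyclin gene in the target list, rose by 0.87 ± 0.21 (0.0206), and the co-receptor gene Cdon by 0.78 ± 0.21 (0.0343). Ptch1, receptor and target of the pathway, did not pass (-0.07 ± 0.22, 0.877). Gli1 was detected on 1 of 12 arrays and Mycn on none, so neither was tested. Of 5 target genes tested, 1 rose and 1 fell, and 2 each adjusted over the list alone, when Ccnd2 (1.25 ± 0.38) and Sfrp1 (-0.51 ± 0.22, both chosen after their values were seen) joined. Of 7 ligand, receptor and transducer genes, 1 rose and 1 fell, also adjusted over the list alone, and neither list shifted (medians -0.07 with mean 0.02, and 0.29, camera adjusted p = 0.933 and 0.562). Hhip no longer passed without tumor sample 1 or 3 (0.051, 0.0611), nor did Ccnd1 without tumor sample 1 or 3 (0.0634, 0.0501) or wild-type sample 1 (0.0649). Cdon failed without any of tumor samples 1, 2 and 3 (0.0949, 0.057, 0.0656), without wild-type sample 1 or 3 (0.103, 0.101), and with the block (0.0507). With only the 6 P0 arrays fitted adjusted p was 0.0695 for Hhip, 0.0881 for Ccnd1 and 0.164 for Cdon.

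Of 11 neural progenitor genes, 3 rose and none fell at P0, also when adjusted over the list alone (median 0.61, or 0.49 with bounded genes at their bound, camera adjusted p = 0.00262, but adjusted p = 0.0947 with an estimated correlation). The glial glutamate transporter Slc1a3 rose by 1.57 ± 0.28 (0.0034), the stem cell factor Sox2 by 2.27 ± 0.53 (0.0159) and Prom1 by 0.94 ± 0.28 (0.0455). Sox2 failed without tumor sample 3 (0.061) or wild-type sample 3 (0.0507), and a second probe detected on all 12 arrays gave -0.04. Prom1 failed without any of tumor samples 1, 2 and 3 (0.068, 0.107, 0.0927), without wild-type sample 1 or 2 (0.146, 0.0999), with the block (0.0571), with no detection filter (0.0555) and with the mean of probes (0.149). With only the 6 arrays fitted Sox2 and Prom1 did not pass (0.0535, 0.148).

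The largest rises at P0 with non-overlapping groups also included the cytochrome P450 gene Cyp2f2 (4.50 ± 0.23, 6.71e-07), the Wnt receptor Fzd10 (4.29 ± 0.33, 9.06e-06) and Shisal1 (4.06 ± 0.22, 7.44e-07). Zfp663 was at least 19.6-fold and the dopamine receptor Drd1 at least 13.8-fold higher than wild-type signals below background (adjusted p = 9.53e-07 and 7.25e-07). The largest falls included the retinoid-binding protein gene Rlbp1 (-2.95 ± 0.41, 0.000733), the mast cell protease genes Cpa3 (-2.77 ± 0.36, 0.000411) and Tpsb2 (at least 3.87-fold lower, adjusted p = 0.000317), the methyltransferase genes Inmt (-2.44 ± 0.36, 0.00116) and Gnmt (-2.30 ± 0.37, 0.00196), Rd3l (-2.33 ± 0.44, 0.00495) and Paqr9 (-2.31 ± 0.27, 0.000217). Spock3 (-2.82 ± 0.74, 0.0281) no longer passed without tumor sample 1 or 3 (0.0737, 0.107) or any of wild-type samples 1, 2 and 3 (0.0567, 0.06, 0.0773).

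None of the planned lists for other cell types shifted at P0. Fibulin-1, Fbln1, a fibroblast gene, rose by 1.97 ± 0.19 (4.09e-05). No member passed among neurons (median -0.41, camera adjusted p = 0.933), granule neurons (0.53, 0.352) and the oligodendrocyte lineage (-0.23, or -0.045 with bounded genes at their bound, 0.965). Nor did any among endothelial cells (0.11, 0.933), interferon response (0.603), immediate early (0.44, 0.106) and sex-linked genes (median -0.43, mean 0.06, 0.933). In the astrocyte list (median -0.41, 0.965) Slc1a3 rose and Aldh1l1 fell (-0.83 ± 0.22, 0.0318). In the pericyte list (median -0.01, mean 0.20, 0.933) Notch3 was the only member to pass. Among macrophage genes (median 0.32, 0.169, but 0.0232 without tumor sample 2) the scavenger receptors Lyve1 (1.11 ± 0.25, 0.0149) and Mrc1 (0.70 ± 0.21, 0.047) rose and Ctss fell (-1.02 ± 0.24, 0.0182). Among fibroblast genes (median -0.05, mean 0.04, 0.933) Fbln1 and Col1a2 (0.99 ± 0.24, 0.0204) rose and Pdgfra fell (-0.79 ± 0.18, 0.0143). Car1 fell in the red blood cell list (-0.65 ± 0.19, 0.0452; median -0.26, 0.383) and Id4 among BMP targets (-0.90 ± 0.21, 0.0177; median 0.50, 0.696). Adjusted over the list alone these counts were unaltered except in the fibroblast list, where 2 rose and 3 fell with Ogn (-0.94 ± 0.29) and Dcn (-0.55 ± 0.17, both chosen after their values were seen).

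Many of these P0 calls for other cell types ended with 1 array left out or with other processing. Adjusted p without tumor samples 1 and 3 was 0.0813 and 0.129 for Aldh1l1, 0.0537 and 0.0705 for Lyve1, 0.085 and 0.0902 for Mrc1, 0.0565 and 0.0556 for Col1a2, 0.0558 and 0.0523 for Pdgfra, and 0.073 and 0.096 for Car1. Without tumor sample 1 it was 0.0537 for Ctss and 0.0614 for Id4, and without tumor sample 2 it was 0.0911 for Mrc1 and 0.0824 for Car1. Without wild-type sample 1 it was 0.0969 for Aldh1l1, 0.0542 for Ctss, 0.101 for Mrc1, 0.0666 for Col1a2 and 0.0905 for Car1. Without wild-type sample 2 it was 0.0602 for Aldh1l1, 0.053 for Id4, 0.0849 for Mrc1 and 0.0985 for Car1, and without wild-type sample 3 it was 0.0608 for Lyve1, 0.0553 for Ctss, 0.0514 for Id4, 0.0824 for Mrc1 and 0.0501 for Car1. The block gave 0.0826 for Mrc1 and 0.0845 for Car1. With only the 6 P0 arrays fitted it was 0.157 for Aldh1l1, 0.0543 for Lyve1, 0.146 for Mrc1, 0.0501 for Ctss, 0.0661 for Col1a2, 0.116 for Pdgfra, 0.188 for Car1 and 0.0914 for Id4. The mean of probes gave 0.136 for Pdgfra and turned Id4 to 0.07 (0.958), and median scaling gave 0.0973 for Mrc1. Car1 also failed with a larger offset (0.0792), no background correction (-0.26, 0.158), cyclic loess (0.0889), median scaling (0.118), quantiles within each BeadChip (0.0552) and the authors' values (0.124). The immediate early list passed without wild-type sample 1 (0.0418) and with no detection filter (0.0285).

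**Figure D2:**
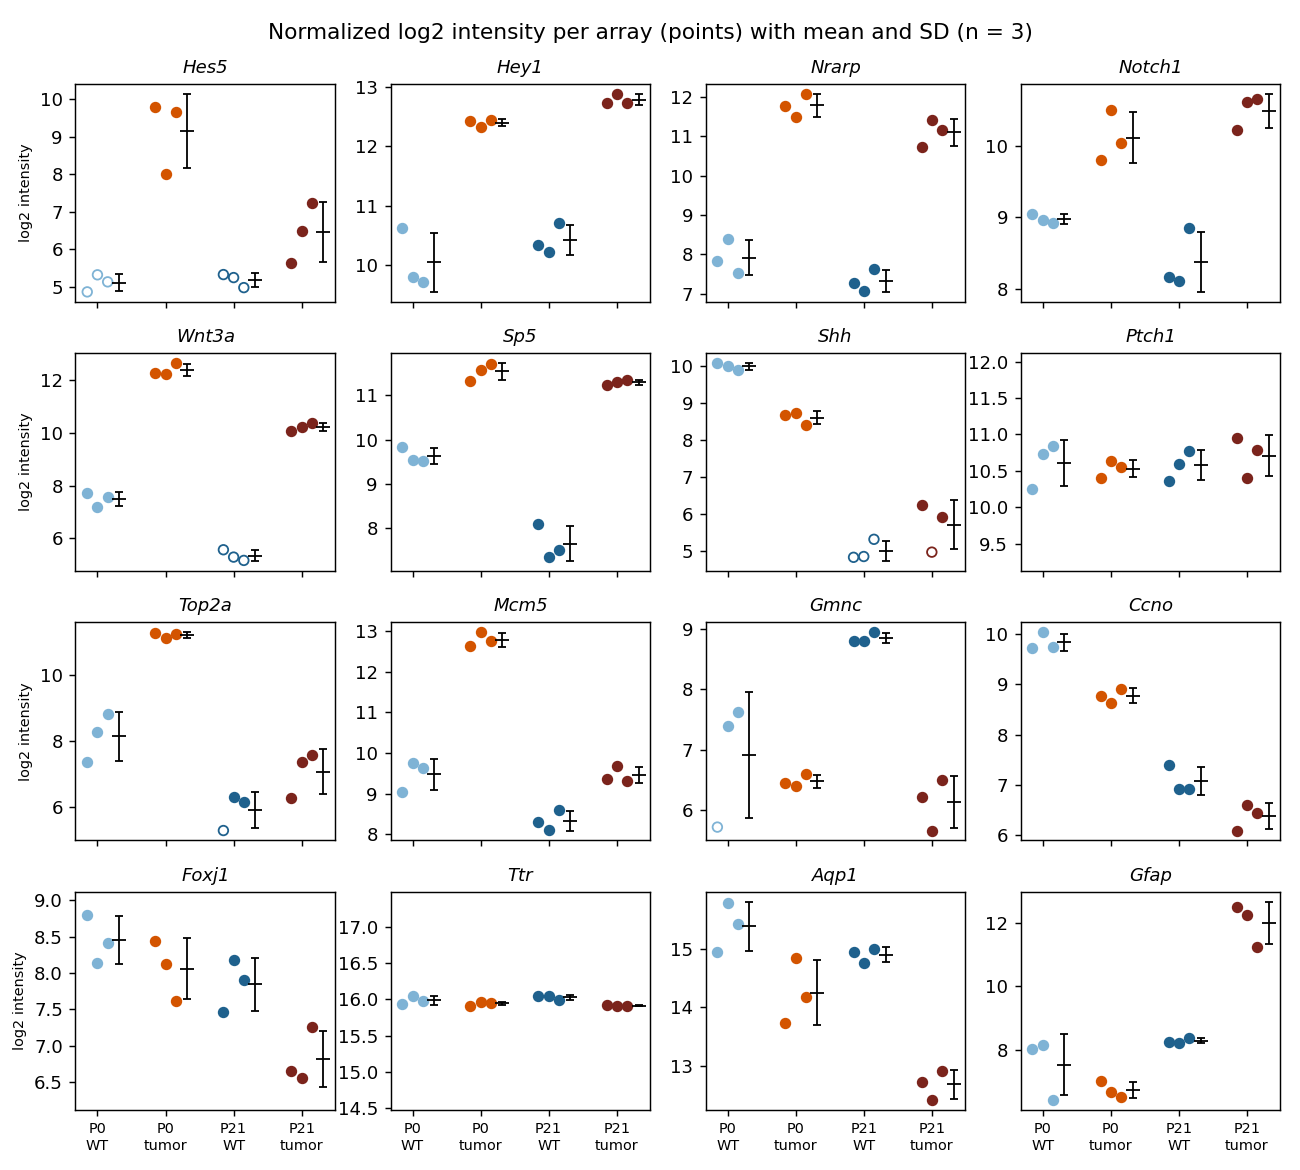
Normalized log2 intensity (y axis, whose range differs between panels) of 16 genes in each array, by group, with filled points detected above background, open points not, and black bars for the mean ± SD (n = 3). Tumor points lie above wild-type points for Nrarp, Hey1 and Wnt3a at both ages, and Mcm5 is 3.30 log2 units higher in tumors at P0 and 1.11 at P21.

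The P21 comparison asked the same question in juvenile mice. Wnt3a was at least 22.3-fold and the Wnt agonist Rspo1 at least 28.4-fold higher than wild-type signals below background (limma adjusted p = 4.17e-08 and 1.34e-06). Notch targets rose again, with Nrarp higher by 3.78 ± 0.27 log2 units (SE, n = 3 per group, 1.83e-06) and Hey1 by 2.37 ± 0.24 (2.79e-05). The shift of the Notch target list was lost with an estimated correlation (camera adjusted p = 0.0526). Gmnc, at the top of the multiciliated program, fell by 2.73 ± 0.40 (6.64-fold lower, 0.000479), and the water channel Aqp1 by 2.21 ± 0.29 (4.63-fold lower, 0.000186). Of the astrocyte, macrophage and fibroblast lists 5 of 7, 6 of 13 and 5 of 12 genes rose, among them Gfap by 3.71 ± 0.42 (7.24e-05), and the shifts of these lists were lost with an estimated correlation (adjusted p = 0.199, 0.142 and 0.142 with an estimated correlation). In all, 2221 genes passed, 1300 higher and 921 lower, and 965 and 529 of these differed by at least 1 log2 unit. The 2 groups did not overlap for 45.0% of genes, against 10% by chance, and for 247 of the passing genes one group was below background on all its arrays. The count was 1429 without tumor sample 2 and 1472 without wild-type sample 2, and median scaling in place of quantile normalization gave 1702 higher and 613 lower. With only the 6 P21 arrays fitted 3178 genes passed, 1605 higher and 1573 lower. Tumor sample 1 stood apart in neuron and oligodendrocyte genes, with list medians 2.93 and 2.81 log2 units above the wild-type mean, and 1922 genes passed without it.

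Of 9 Notch target genes, 7 rose and none fell at P21, and 8 rose adjusted over the list alone (median 1.75, camera adjusted p = 3.26e-06, but adjusted p = 0.0526 with an estimated correlation). Dtx1, a ubiquitin ligase of the pathway, rose by 2.42 ± 0.30 (0.000122), Heyl by 2.23 ± 0.30 (0.000267) and Hes1 by 1.34 ± 0.27 (0.00418). Hes5 was below background in wild-type CP, with a bound of at least 1.65-fold, and did not pass (adjusted p = 0.0772) except without tumor sample 1 (0.0258), with the mean of probes (0.0379), with only the 6 P21 arrays (0.0456) or with the covariate (0.0145). Of 12 receptors, ligands and cofactors, Notch1 and Maml2 (0.78 ± 0.17, 0.00638) rose and Maml1 fell (-1.36 ± 0.25, 0.00239), also adjusted over the list alone. The list did not shift (median 0.21, camera adjusted p = 0.569). The Maml1 difference turned positive with cyclic loess (0.39), median scaling (0.53), no background correction (0.11), the authors' values (0.11) and without wild-type sample 1, 2 or 3 (0.25, 0.19, 0.13), and its other probe gave 0.19. With the mean of probes it was -0.58 (0.0637).

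Of 7 Wnt target genes, 6 rose and 1 fell at P21, also when adjusted over the list alone (median 2.43, or 2.07 with bounded genes at their bound, camera adjusted p = 3.26e-06, and adjusted p = 0.0363 with an estimated correlation). Sp5 rose by 3.64 ± 0.22 (4.3e-07), the feedback inhibitors Nkd2 by 3.18 ± 0.22 (1.35e-06) and Nkd1 by 2.60 ± 0.22 (7.2e-06), and Lgr5 at least 4.2-fold (adjusted p = 0.00017). The one that fell was Lef1, a transcription factor of the pathway (-2.14 ± 0.39, 0.00211). Of 15 CP and roof plate factors, Wnt3a, Rspo1 and Rspo3 (1.32 ± 0.37, 0.0273) rose and none fell, also adjusted over the list alone (median 0.42, camera adjusted p = 0.00125, but adjusted p = 0.097 with an estimated correlation, and 0.0817 with probes detected on all 12 arrays). Rspo3 failed without tumor sample 1 or 2 (0.0761, 0.107) or wild-type sample 2 or 3 (0.101, 0.0787), with no background correction (0.0548) or with the mean of probes (0.0752). Otx2 (-0.20 ± 0.26, 0.677) and Lmx1a (0.38 ± 0.20, 0.24) did not pass.

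Of 15 mitosis genes, 2 rose and none fell at P21, Cdc20 (1.15 ± 0.27, 0.00998), which activates the anaphase-promoting complex, and Kif23 (1.09 ± 0.34, 0.0433), with Cdc20 alone left when adjusted over the list alone. The list shifted up (median 0.58, camera adjusted p = 0.00876) but adjusted p = 0.329 with an estimated correlation, 0.0523 without tumor sample 3 and 0.141 with probes detected on all 12 arrays. Cdc20 failed without tumor sample 2 (0.0554) or wild-type sample 2 (0.0512). Kif23, for which another probe went the opposite way, failed without tumor sample 2 or 3 (0.168, 0.0992), without any of wild-type samples 1, 2 and 3 (0.12, 0.147, 0.0682), with the replicate number as a block (0.0508), with no detection filter (0.0649) and with the mean of probes (0.02, 0.967). Of 19 DNA replication genes, 4 rose and 2 fell, also adjusted over the list alone, with no shift of the list (median 0.12, camera adjusted p = 0.484). Mcm5 (1.11 ± 0.23, 0.00463), Mcm4 (0.77 ± 0.20, 0.019), the licensing factor Cdt1 (1.25 ± 0.22, 0.00177) and Tk1 (at least 1.83-fold, adjusted p = 0.043) rose, while E2f1, a transcription factor of S-phase genes (-1.76 ± 0.21, 9.3e-05), and Pcna (-1.09 ± 0.21, 0.00345) fell. Tk1 failed without tumor sample 2 or 3 (0.143, 0.152) or any of wild-type samples 1, 2 and 3 (0.0813, 0.126, 0.114), with a larger offset (0.124), no background correction (0.277), the authors' values (0.212), no detection filter (0.069) or the mean of probes (0.273). Of 7 CDK inhibitors, Cdkn2b (1.92 ± 0.28, 0.000429) and Cdkn2c (1.15 ± 0.27, 0.0111) rose and Cdkn1c fell (-1.39 ± 0.18, 0.000186), also adjusted over the list alone (median 0.11, camera adjusted p = 0.677). Cdkn2c failed without tumor sample 2 (0.059) or wild-type sample 2 (0.0596).

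Of 11 multiciliated cell regulators, 4 fell and none rose at P21, also when adjusted over the list alone, led by Gmnc. Trp73 was at least 2.07-fold lower (adjusted p = 0.0119), Foxj1 fell by 1.02 ± 0.29 (0.0271) and Ccno by 0.70 ± 0.21 (0.0342), while Mcidas was below background in both groups. Trp73 failed without wild-type sample 2 (0.0566), and Foxj1 without tumor sample 1 or 2 (0.0771, 0.114) or wild-type sample 2 or 3 (0.122, 0.0802), with no background correction (0.052), cyclic loess (0.0541) or median scaling (0.109). Ccno failed without tumor sample 1 or 3 (0.129, 0.0706), without any of wild-type samples 1, 2 and 3 (0.154, 0.059, 0.0528), with the replicate block (0.0765), a larger offset (0.0526), no background correction (0.0986), cyclic loess (0.0723), median scaling (0.22) and the authors' values (0.0838). The list did not shift (median -0.46, camera adjusted p = 0.0892) except without wild-type sample 3 (0.0481), with cyclic loess (0.0438) or with median scaling (0.0454). Of 39 motile cilium components, 10 fell and 2 rose, and 11 fell and 2 rose adjusted over the list alone (median -0.46, camera adjusted p = 0.00391, but adjusted p = 0.235 with an estimated correlation). Ccdc113 fell by 1.41 ± 0.17 (8.67e-05) and Ak8 by 1.25 ± 0.19 (0.000535), while Fam183b (2.43 ± 0.40, 0.00106) and Tppp3 (1.68 ± 0.31, 0.00225) rose. Of 23 intraflagellar transport and primary cilium genes Ift57 fell (-1.32 ± 0.28, 0.00603), the only one to pass, also adjusted over the list alone. That list did not shift (median -0.21, camera adjusted p = 0.0621) but did without tumor sample 1 or 2 (0.0496, 0.0448) or wild-type sample 3 (0.0481), with no background correction (0.0487), median scaling (0.0454), no detection filter (0.0265), only the 6 P21 arrays (0.0201) or the covariate (0.0383).

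Of 31 CP epithelial genes, 12 fell and none rose at P21, and 13 fell adjusted over the list alone (median -0.56, camera adjusted p = 6.53e-06, but adjusted p = 0.0899 with an estimated correlation). Beside Aqp1, Trpv4 fell by 2.46 ± 0.21 (6.64e-06), the potassium channel subunit Kcne2 by 1.72 ± 0.18 (4.25e-05) and Ace by 1.63 ± 0.24 (0.000521). Ttr again did not pass (-0.11 ± 0.15, 0.669), with a signal as near the top of the scale as at P0, so no lack of change can be read from it.

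Among 7 Hedgehog ligand, receptor and transducer genes at P21, the transcription factor genes Gli3 (1.55 ± 0.32, 0.00491) and Gli2 (0.97 ± 0.26, 0.0191) and the co-receptor gene Cdon (0.89 ± 0.21, 0.0109) rose and none fell. Adjusted over the list alone 5 rose, with Sufu (0.81 ± 0.29, chosen after its values were seen) and Shh as the added ones. Shh was below background in all wild-type arrays and detected in 2 of 3 tumor arrays, with no fold to give, and did not pass over all genes (0.114) except without tumor sample 2 (0.0105). The list shifted up (median 0.81, camera adjusted p = 0.00476) but adjusted p = 0.0787 with an estimated correlation. Gli2 failed without tumor sample 2 (0.0941) or wild-type sample 2 or 3 (0.0709, 0.0879), and Cdon without tumor sample 2 (0.0587). Of the 5 targets tested, Sfrp1 fell (-1.20 ± 0.22, 0.00194), the only one to pass, also adjusted over the list alone (median -0.37, camera adjusted p = 0.435), but with the mean of probes it was -0.67 and did not pass (0.151). Ptch1 did not pass (0.13 ± 0.22, 0.746).

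Of 11 neural progenitor genes, 4 rose and none fell at P21, and 5 rose adjusted over the list alone with Igf2bp1 (0.83 ± 0.30, chosen after its values were seen). Slc1a3 rose by 3.86 ± 0.28 (1.72e-06), the intermediate filament genes Nes by 2.68 ± 0.37 (0.000308) and Vim by 2.07 ± 0.24 (7.32e-05), and Prom1 by 2.47 ± 0.28 (6.03e-05). The list shifted up (median 0.83, camera adjusted p = 0.000954), but adjusted p = 0.0787 with an estimated correlation. Slc1a3 is also in the astrocyte list, described next.

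Of 7 astrocyte genes, 5 rose and 1 fell at P21, also adjusted over the list alone (median 2.25, camera adjusted p = 0.00106, but adjusted p = 0.199 with an estimated correlation). The water channel Aqp4 rose by 4.06 ± 0.70 (0.00148), Gja1 by 2.25 ± 0.29 (0.000163) and Aldoc by 2.06 ± 0.57 (0.0241, chosen after its values were seen), and Aldh1l1 fell by 1.10 ± 0.22 (0.00436). Aldoc failed without tumor sample 2 (0.0517) or any of wild-type samples 1, 2 and 3 (0.0553, 0.0909, 0.0615). The list's median above the wild-type mean was 3.74, 2.21 and 1.67 in tumor samples 1, 2 and 3. The oligodendrocyte list was at 2.81, -1.24 and -1.84 in the same arrays and the neuron list at 2.93, -0.12 and -0.98. Neither of these shifted over the 3 arrays (oligodendrocyte median 0.03 and mean -0.01, camera adjusted p = 0.569; neurons 0.60, 0.61), nor did granule neuron genes (0.29, 0.622). Without tumor sample 1 both shifted down (neurons adjusted p = 0.0312, oligodendrocytes 0.00093). No neuron or granule neuron gene passed, and Cldn11 was the one oligodendrocyte gene to rise (1.22 ± 0.20, 0.000988), also adjusted over the list alone.

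Of 13 macrophage and microglia genes, 6 rose and none fell at P21, and 9 rose adjusted over the list alone (median 1.17, camera adjusted p = 3.26e-06, but adjusted p = 0.142 with an estimated correlation). Lyve1 was at least 3.57-fold higher (adjusted p = 4.19e-05), Mrc1 rose by 1.76 ± 0.21 (8.67e-05) and the fractalkine receptor Cx3cr1 by 1.48 ± 0.19 (0.000185). The list's median above the wild-type mean was 0.59, 1.36 and 1.64 in tumor samples 1, 2 and 3. Of 12 fibroblast and meningeal genes, 5 rose and 1 fell, also adjusted over the list alone (median 0.66, camera adjusted p = 0.00876, but adjusted p = 0.142 with an estimated correlation). The collagen genes Col1a2 (2.97 ± 0.24, 4.83e-06) and Col1a1 (1.42 ± 0.33, 0.00997), Slc6a13 (2.67 ± 0.38, 0.00039), the retinoic acid-synthesizing Aldh1a2 (2.01 ± 0.26, 0.000164) and Fbln1 (1.19 ± 0.19, 0.000708) rose, and Pdgfra fell (-0.86 ± 0.18, 0.00515), the last 2 chosen after their values were seen. That list's median above the wild-type mean was 0.39, 0.91 and 0.73 in the same arrays.

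Of 10 pericyte and smooth muscle genes, Acta2 (3.02 ± 0.41, 0.000238), Notch3 (1.75 ± 0.35, 0.00389) and Tagln (at least 1.79-fold, adjusted p = 0.00669) rose and Abcc9 fell (-1.10 ± 0.28, 0.016), and 4 rose and 3 fell adjusted over the list alone, without a shift of the list (median 0.17, camera adjusted p = 0.569). Pdgfrb, Des and Kcnj8 were the added ones, chosen after their values were seen. Of 12 endothelial genes, Vwf (1.33 ± 0.29, 0.00686) and Cldn5 (1.28 ± 0.28, 0.00687) rose, also adjusted over the list alone (median 0.33, 0.438, but 0.0317 without wild-type sample 3). Immediate early genes shifted up (median 0.91, camera adjusted p = 0.00696, but adjusted p = 0.096 with an estimated correlation), and Egr2 (0.96 ± 0.19, 0.00405) and Dusp1 (0.86 ± 0.24, 0.0273) rose. Adjusted over the list alone 5 of 6 rose, with Fos, Egr1 and Junb, chosen after their values were seen. Ifit3 rose (1.58 ± 0.30, 0.00281) and Bst2 fell (-1.54 ± 0.41, 0.0203) among 8 interferon response genes (median -0.12, 0.731), and Id4 rose among BMP targets (1.11 ± 0.21, 0.00305; median 0.14, 0.322), both also adjusted over the list alone, and with the mean of probes Id4 did not pass (0.0844). No red blood cell gene passed (median -0.56, 0.0833, but 0.0438 with cyclic loess and 0.0231 with median scaling). The Y-linked genes Eif2s3y (-3.44 ± 1.07, 0.0426) and Uty (-1.19 ± 0.34, 0.0298) were lower, and 3 were lower adjusted over the list alone with Kdm5d (-1.93 ± 0.71, chosen after its values were seen), with no shift of the list (median -1.56, 0.0949, but 0.00307 without tumor sample 2 and 0.0454 with median scaling). Abcc9 failed without tumor sample 2 (0.0817) or wild-type sample 1 or 3 (0.0657, 0.0522) or with median scaling (0.0786). Bst2 failed without tumor sample 1 or 2 (0.0623, 0.0745) or wild-type sample 1 or 2 (0.0649, 0.0827), and Dusp1 without tumor sample 1 (0.0959) or wild-type samples 1, 2 or 3 (0.0756, 0.105, 0.0598). Eif2s3y failed without tumor sample 1 or 3 (0.143, 0.151) or any of wild-type samples 1, 2 and 3 (0.107, 0.121, 0.0921), with no background correction (0.0616), the authors' values (0.0563), no detection filter (0.0793), probes detected on all 12 arrays (-0.56, 0.197), only the 6 P21 arrays (0.106) or the covariate (0.0596). Uty failed without tumor sample 1 or 3 (0.0722, 0.107) or wild-type sample 2 (0.14), with no background correction (0.0544), median scaling (0.0553) or the mean of probes (0.186).

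The largest rises at P21 with non-overlapping groups were those of Cyp2f2, 122-fold higher (6.94 ± 0.23, 3.75e-09), Shisal1 (5.88 ± 0.22, 9.13e-09), Fzd10os (5.59 ± 0.18, 3.75e-09) and the complement gene C4a (5.27 ± 0.35, 9.47e-07), whose signal is uncertain because of its near-identical copy C4b. They also included vitronectin, Vtn (5.22 ± 0.25, 6.76e-08), the lipid acyltransferase gene Mboat1 (4.98 ± 0.23, 6.76e-08) and Fzd10, at least 24.8-fold higher (adjusted p = 8.07e-07). The largest falls were those of the retinol-oxidizing Adh1 (-3.35 ± 0.44, 0.000185), the protease gene Tmprss11a (-3.30 ± 0.30, 1.34e-05), the melanin synthesis gene Dct (-3.27 ± 0.28, 6.1e-06), Vpreb1 (-3.16 ± 0.52, 0.000995), Pik3c2g (-3.04 ± 0.28, 1.56e-05), Dpep1 (-3.00 ± 0.30, 2.84e-05), Myrip (-2.91 ± 0.31, 4.23e-05) and Sult1c2, at least 5.86-fold lower (adjusted p = 0.000294).

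**Figure D3:**
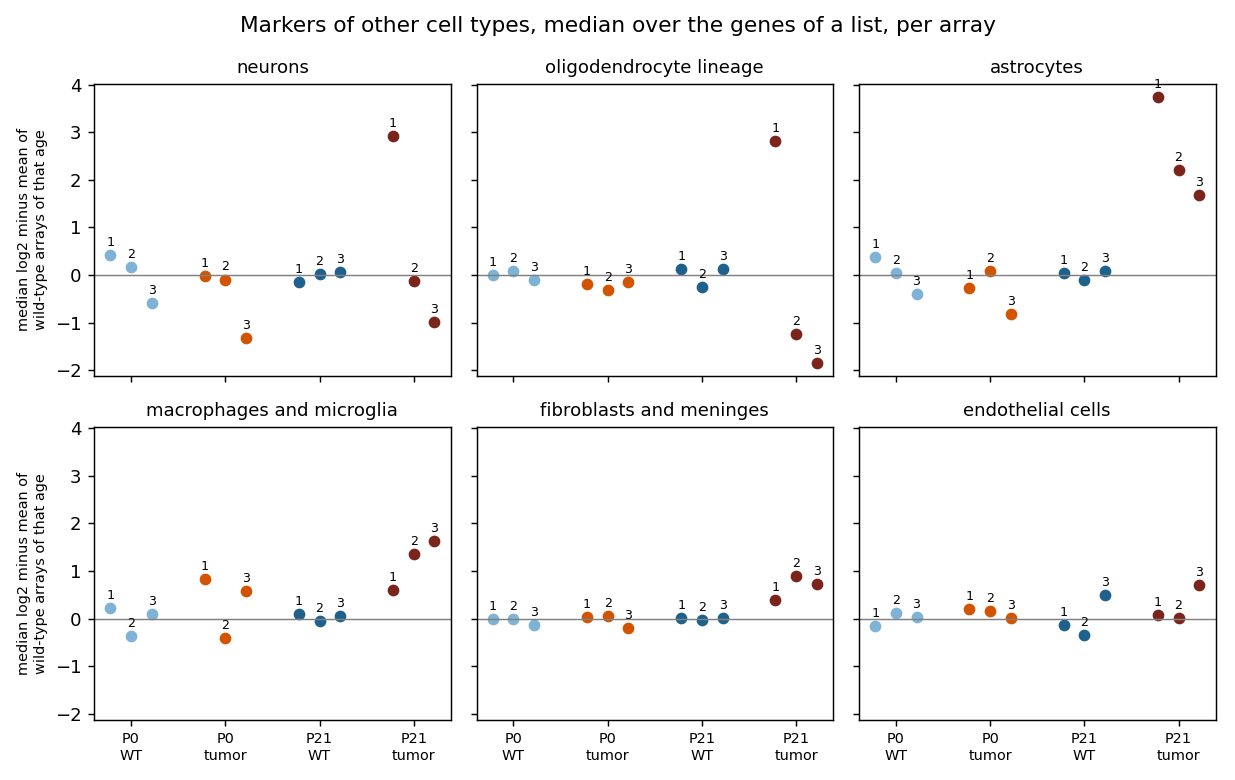
Median log2 intensity of 6 cell type lists in each array (points, numbered by replicate) minus the mean of the wild-type arrays of that age, in log2 units, by group (n = 3). Neuron and oligodendrocyte lists reach 2.93 and 2.81 in P21 tumor replicate 1 and lie below 0 in replicates 2 and 3, while the astrocyte list lies at 1.67 or above in all 3.

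The overlap of both comparisons asked how far the tumors shared changes across ages, from separate control arrays. Nrarp, Hey1, Wnt3a, Axin2 and Cyp2f2 were among 309 genes higher in tumors at both ages, where independent lists would share 65.0 (Fisher's exact test, p = 1.31e-145). Ccno, Tekt1, Trpv4, Ace and Aqp1 were among 357 genes lower at both ages, where 57.9 would be shared (Fisher's exact test, p = 1.52e-213). Opposite directions were rare, with 9 genes higher at P0 and lower at P21 (46.1 for independent lists) and 14 the other way (81.7). Genes are correlated, and one pooled spread per gene served both ages. The Fisher p-values, which treat genes as independent, may therefore be far too small. Across all genes, which are not independent replicates, the 2 sets of log2 differences correlated with r = 0.49 and rho = 0.44. The 666 genes shared in one direction became 406 without P0 tumor sample 3, 335 with only the 6 arrays of each comparison fitted, and 1001 with the level of ribosomal and oxidative phosphorylation genes as a covariate, chosen after the data were seen.

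**Figure D4:**
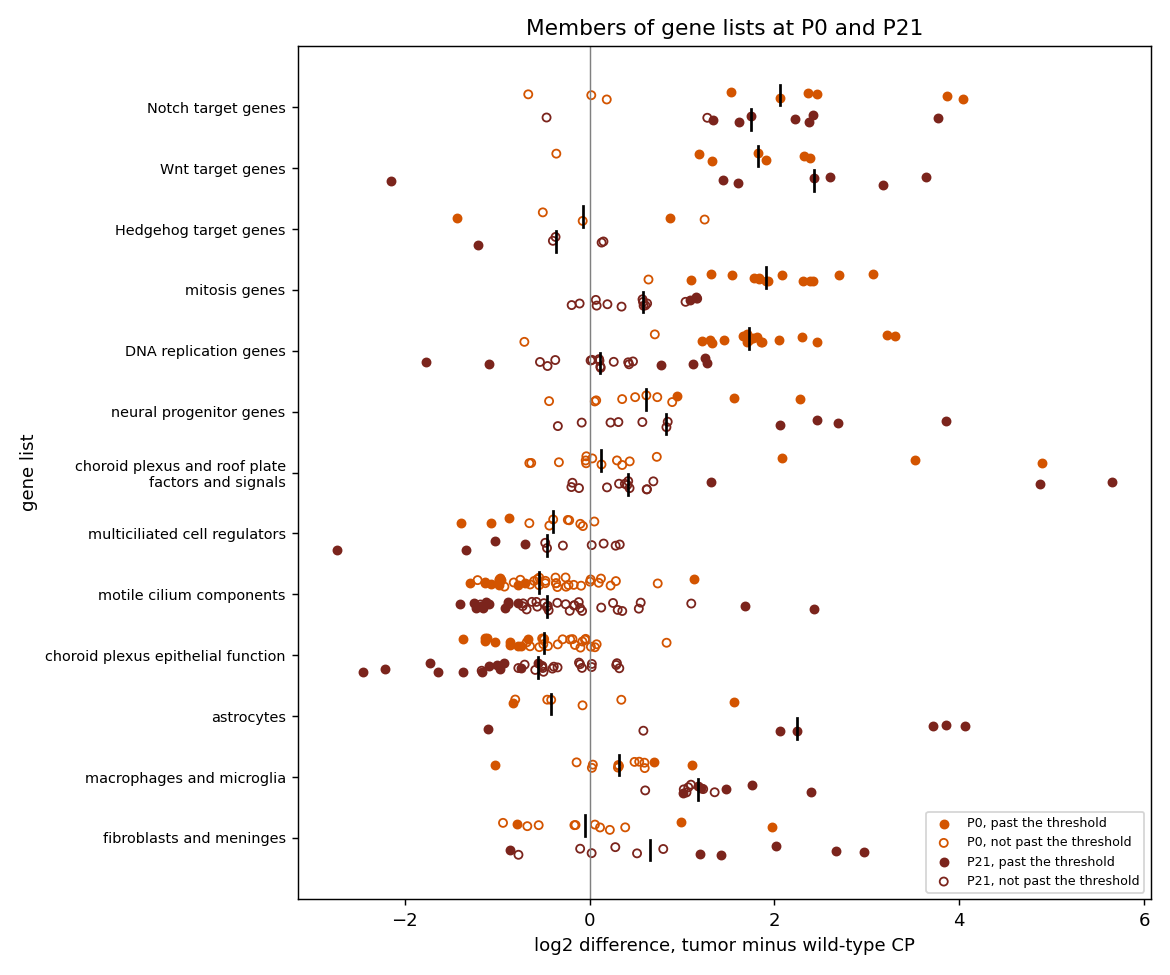
Log2 difference, tumor minus wild-type CP, of each member of 13 gene lists (points, filled where past the adjusted p threshold, open where not) at P0 (orange, upper) and P21 (dark red, lower), with list medians as black bars. Mitosis and DNA replication medians are 1.91 and 1.73 at P0 against 0.58 and 0.12 at P21, and Wnt target medians 1.82 and 2.43.

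The difference between the 2 tumor effects, P21 minus P0, was tested as an interaction, which compares across BeadChips. Cell cycle genes rose less at P21. For DNA replication genes the median interaction was -1.60 log2 units (camera adjusted p = 3.83e-19, and adjusted p = 0.0184 with an estimated correlation), with 11 of 19 members lower and none higher, and 17 lower adjusted over the list alone. For mitosis genes it was -1.36 (camera adjusted p = 5.26e-13, but adjusted p = 0.0704 with an estimated correlation), with 9 of 15 lower and 12 adjusted over the list alone. E2f1 (-3.07 ± 0.30, SE, 0.000182), the replication factor Mcm10 (-3.03 ± 0.30, 0.000198) and Ccne2, a cyclin gene of the G1 to S transition (-2.90 ± 0.57, 0.0127), were among the lowest. Astrocyte genes rose more at P21 (median 2.29, camera adjusted p = 9.86e-05, but adjusted p = 0.254 with an estimated correlation; 4 of 7 higher, and 5 adjusted over the list alone), with Gfap at 4.52 ± 0.60 (0.00144). In all, 549 genes passed, 388 higher and 161 lower, and Nrarp (-0.09 ± 0.39, 0.935) and Hey1 (0.01 ± 0.34, 0.993) did not. The count was 313 without P0 tumor sample 3, 280 without P21 tumor sample 2, 335, 315 and 337 without P21 wild-type samples 1, 2 and 3, and 346 with probes detected on all 12 arrays.

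Age comparisons within a genotype describe development, but each age lay on its own BeadChip, so age and BeadChip cannot be told apart. In wild-type CP 2518 genes differed, 913 higher and 1605 lower at P21. Shh was at least 19.0-fold lower at P21 (adjusted p = 9.79e-07). The protease gene Klk4 (-6.75 ± 0.20, SE, n = 3 per group, 2.39e-09), the RNA-binding protein gene Igf2bp3 (-5.28 ± 0.28, 5.34e-07) and the neutrophil gene S100a9 (-4.52 ± 0.46, 4.37e-05) also fell, and so did Stfa1 (at least 35.9-fold, adjusted p = 5.33e-06) and Pde6c (at least 31.7-fold, 1.23e-07). Hr (4.02 ± 0.38, 2.9e-05), Dct (3.99 ± 0.28, 4.21e-06), Kalrn (3.96 ± 0.27, 4.21e-06) and Il17re (3.77 ± 0.31, 1.06e-05) rose, as did Sgpp2 (at least 10.4-fold, adjusted p = 0.000344) and Tns4 (at least 8.46-fold, 4.25e-06). The count was 1654, 1667 and 1658 without P21 wild-type samples 1, 2 and 3.

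In tumors 2501 genes differed with age, 1230 higher and 1271 lower at P21, or 1586 and 937 with median scaling. The largest rises were those of the mitochondrial carrier gene Slc25a18 (6.26 ± 0.34, SE, 3.32e-07), C4a (6.10 ± 0.35, 4.19e-07), C4b (5.91 ± 0.36, 5.38e-07), Aqp4 (5.61 ± 0.70, 0.000138), Gfap (5.26 ± 0.42, 4.04e-06) and the receptor gene Gpr37l1 (at least 48.9-fold, adjusted p = 9.33e-07). Klk4 (at least 48.7-fold, adjusted p = 5.94e-09), Stfa1 (at least 43.2-fold, 1.58e-06), Igf2bp3 (-5.32 ± 0.28, 3.32e-07), S100a8 (-5.10 ± 0.49, 1.57e-05), S100a9 (at least 21.2-fold, 1.97e-05) and Cstdc4 (at least 11.6-fold, 5.36e-05) fell. With only probes detected on all 12 arrays another Igf2bp3 probe gave -0.03 in wild-type CP and -0.54 in tumors, and neither passed.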

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

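The counts over other splits of the arrays were planned, and the tests of cell sources, background signals and precursor genes in this part were chosen only after the results were seen.

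The tumor effect differed between P21 and P0 for 549 genes in the interaction test. Of 100 combinations of splits within the ages, 5 gave as many genes, the real one included, and the highest of the others gave 1440, so chance was not excluded by this count. The 4 others kept the true groups at P21 and mixed tumor and wild-type arrays at P0, so that their counts took up the P21 difference itself, which shows a structure of the samples. The highest count with the true groups only at P0 was 90, and with the true groups at neither age it was 1.

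Of 10 splits of the 6 arrays, 1 gave as many genes as the real one, that one itself, at P0 (1397 genes, highest other 111) and at P21 (2221, highest other 1). The same count was 1 of 10 with age in wild-type CP (2518, highest other 0) and in tumors (2501, highest other 1), and 1 of 10 for lists at P0 (9, highest other 8). For lists at P21 it was 4 of 10 (12, highest other 13). The other splits gave 0 to 8 lists at P0 and 6 to 13 at P21. The number of lists called at the preset correlation thus hardly tells the real groups from mixed ones. With 10 splits no share under 0.05 can be reached. Among the 4 P0 splits that part all 3 replicate numbers, each of the others gave 0 genes. For the overlap of both ages, 1 of 100 combinations gave as many shared genes (666, highest other 30). No other split gave more than 111 genes at P0 or 1 at P21, so this count follows from the numbers of genes called and shows nothing about the sharing.

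Gene lists differed between the ages by the same interaction test. Medians were -1.36 log2 units for mitosis genes and -1.60 for DNA replication genes (camera adjusted p = 5.26e-13 and 3.83e-19, and adjusted p = 0.0704 and 0.0184 with an estimated correlation, so only the latter kept its call). They were 2.29 for astrocytes (9.86e-05, but adjusted p = 0.254 with an estimated correlation), 0.98 for macrophages (0.000151, but adjusted p = 0.348 with an estimated correlation; 3 members higher and 6 adjusted over the list alone) and 0.86 for fibroblasts (0.0193, but adjusted p = 0.254 with an estimated correlation; 3 members higher, and 4 higher and 1 lower adjusted over the list alone). The macrophage median was 0.47 without P0 tumor sample 2 (0.0145), and the fibroblast call ended without P0 wild-type sample 2 (0.0576).

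Single genes also differed between the ages. Complement genes C4a (5.59 ± 0.49 log2, SE, adjusted p = 0.000165) and C4b (5.35 ± 0.50, 0.000165), which are near-identical copies, the mitochondrial carrier gene Slc25a18 (5.20 ± 0.48, 0.000165), Mmd2 (4.78 ± 0.89, 0.00948) and Gfap (4.52 ± 0.60, 0.00144) had the highest interactions. The retinoid isomerase gene Rpe65 also passed (4.38 ± 0.53, 0.000729), but its P0 wild-type signals were below background, so neither its size nor its rank is given by this value. E2f1 (-3.07 ± 0.30, 0.000182), Mcm10 (-3.03 ± 0.30, 0.000198), Ddn (-2.98 ± 0.45, 0.00288), H2ac12 (-2.95 ± 0.46, 0.00393), Ccne2 (-2.90 ± 0.57, 0.0127) and Cdca2 (-2.82 ± 0.35, 0.000884) had the lowest. All 12 passed with any single array left out. Shh had an interaction of 2.10 ± 0.41 (0.0118), but its P21 wild-type signals were below background, so this value gives no size for the difference between the ages.

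Hes5 had an interaction of -2.77 ± 0.65 (adjusted p = 0.0305), with wild-type signals below background at both ages, so its size is not given by this value. The call ended without P0 tumor sample 1 or 3 (0.0717, 0.0906), P0 wild-type sample 1 or 3 (0.0601, 0.0606), P21 tumor sample 2 (0.0741) or P21 wild-type sample 2 or 3 (0.0797, 0.0606). For Gmnc it was -2.30 ± 0.57 (0.0414). That call ended without P0 tumor sample 1, 2 or 3 (0.0782, 0.059, 0.106), P21 tumor sample 1 or 2 (0.0526, 0.116) or P21 wild-type sample 1, 2 or 3 (0.0862, 0.0945, 0.101).

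Of 3979 tested probes without a gene name, 194 passed in the P0 tumor comparison (104 higher, 90 lower) and 398 at P21 (256 higher, 142 lower), a signal outside the named genes.

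Neuron and oligodendrocyte genes were high in P21 tumor sample 1, and astrocyte genes in all 3 P21 tumor samples. In that array the lower of both list medians was 2.81 above the wild-type mean, with Syt1 at 2.93 and the brightest P21 probe of Mbp at 3.43, though a second Mbp probe stayed at -0.00. Hindbrain tissue next to the CP is a candidate source of this signal, since in that array 13 neuron genes outside all lists had a median of 3.37 and 8 such oligodendrocyte genes of 2.12. The 3 wild-type P21 arrays also detected 9 of 11 neuron genes and 10 of 10 oligodendrocyte genes, which no other list holds. Whether such tissue also gave the astrocyte signal of samples 2 and 3 is not decided, since oligodendrocyte genes went both ways there. The higher oligodendrocyte list median was -1.24, while Slc1a3 lay at 4.02 and 3.20 and Gja1 at 2.21 and 1.67. The 13 neuron genes outside all lists lay at a median of -0.55 and -1.54 there (SD 0.68 and 1.13). Of these, Uchl1 (0.34 and 0.25) and Nsg2 (0.62 and 0.77) were higher in both samples, and Slc32a1 (0.05) in sample 2. The brightest P21 probe of Mbp lay at -1.49 and -2.72 in these samples, the third at -2.06 and -1.94 and the fourth at -0.72 and -0.96. Cldn11, however, lay at 1.20 and 1.05, the second Mbp probe at 0.36 and 0.34 and the fifth at 0.00 and 0.11. The 8 oligodendrocyte genes outside the lists lay at a median of 0.03 and -0.35 (SD 1.51 and 1.47). Without sample 1, 5 astrocyte genes were still higher (Aqp4 by 3.76, Slc1a3 by 3.61, Gfap by 3.46, Gja1 by 1.94 and Aldoc by 1.23, of 7 genes of which 6 are detected in wild-type CP and 1 is in another list), while Aldh1l1 fell by 1.13 (adjusted p = 0.00963) and Slc1a2 was at -0.06 (0.946), and tumor cells and glia beside the tumor cannot be told apart as their source, because tissue source goes with genotype.

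Mitosis and DNA replication genes rose less in P21 than in P0 tumors, though only the DNA replication list kept its interaction call with an estimated correlation. Signals at background that hide a rise at P21 are argued against for the 25 of 34 genes detected on all 6 P21 arrays. In these the P0 effect exceeded the P21 effect by a median of 1.54 (SD 0.78). Genes at background on some P21 array were left out, so for them the question is not decided. The median P21 difference was 0.11 in the 25 genes and 0.30 over all 34. Granule neuron precursors of the cerebellum in the P0 tumor samples cannot be told apart from dividing tumor cells, since Atoh1 was below background and only 2 precursor genes were measured (median 0.83, Barhl1 0.53 ± 0.32, adjusted p = 0.34, and Zic2 1.13 ± 0.46, adjusted p = 0.144). The granule neuron list, 4 of whose 5 genes are detected in all P0 wild-type arrays and none of which another list holds, lay at 1.07, 0.63 and -0.02 in P0 tumor samples 1, 2 and 3. A fall of tumor cell division with age stays open as a hypothesis and was not tested apart from the BeadChip.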

How the results depend on the processing

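The alternatives in this part were planned, except the covariate, which was chosen after the data were seen. Across all alternatives, 3689 values of named genes kept direction and side of the threshold, 205 no longer passed, 11 newly passed and 9 changed sign. For lists these numbers were 1070, 36, 24 and 2, and of the main counts 143 stayed within 1.5 times and 25 did not.

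Leaving out each array in turn gave 730 to 1721 genes at P0, 1429 to 1922 at P21, 280 to 723 for the interaction, 1654 to 2514 with age in wild-type CP, 1685 to 2759 with age in tumors, 406 to 671 shared genes, and 7 to 11 lists at P0 and 11 to 15 at P21. Fewer arrays lower the power of the test, which cannot account for counts that rose. Without P0 tumor sample 2 these were 1721 genes at P0 against 1397 and 723 interaction genes against 549. No further cause was tested. P21 without tumor sample 1 gave 1922 genes and P0 without wild-type sample 1 gave 1058.

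Fitting only the 6 arrays of the comparison gave 561 genes at P0, 3178 at P21 and 335 shared genes, with a spread estimated from those arrays alone. The fit over all arrays gave 1397 at P0 and 2221 at P21. Mean correlations with the own group were 0.946 to 0.978 at P0, 0.949 to 0.972 in P21 tumors and 0.990 in P21 wild-type CP. The pooled spread may therefore be too small for P0 and too large for P21. Requiring detection on all 12 arrays gave 346 interaction genes, with fewer genes tested. An estimated correlation left 4 shifted lists at P0 and 1 at P21. Array weights gave 5964 genes at P0, 5529 at P21, 4136 for the interaction, 5232 and 7596 with age in wild-type CP and tumors, and 2650 shared genes, but the weights (0.171 to 16.4) did not converge, so these counts carry no weight. The covariate gave 2519 genes at P0 and 1001 shared genes, and the cause was not tested.

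The replicate block gave 1410 genes at P0 (655 higher, 755 lower) with 7 lists, 2407 at P21 with 12 lists, 611 interaction genes and 673 shared genes. At P0 it ended the calls of Car1, Mrc1, Prom1, Bbs4 and Cdon and of the multiciliated and roof plate lists, at P21 those of Ccno (0.0765) and Kif23 (0.0508), and changed no other call of a named gene or list. At P21 samples share only a number (r = -0.08, -0.03 and -0.14), and no sample correlated best with its own number.

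Median scaling moved the split of P21 calls from 58.5% to 73.5% higher, that of tumor age calls from 49.2% to 62.9%, and the median interaction of all genes to 0.12. With only 6 arrays the P0 split moved from 44.3% to 58.1% higher and the P21 split from 58.5% to 50.5%.

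Maml1 at P21 changed sign with no background correction (0.11), cyclic loess (0.39), median scaling (0.53) and the authors' values (0.11), and without P21 wild-type sample 1, 2 or 3 (0.25, 0.19, 0.13). Its 2 probes gave -1.36 and 0.19, with nearly equal brightness, so the choice of the brighter one set the sign without those arrays, and for the others the cause was not tested. With single arrays left out it ran from -1.44 to 0.25. Sox2 at P0 was -0.041 with probes detected on all 12 arrays, which left only its dimmer probe, and Id4 at P0 was 0.065 with the mean of its 2 probes, which had opposite signs. Without P21 tumor sample 1 the neuron list (adjusted p = 0.0312) and the oligodendrocyte list (0.00093) shifted down, and over all arrays left out these p-values reached 0.710 and 0.670. Htr2c at P0 was -0.18 (0.801) with the mean of probes, and -0.34 (0.726) and -0.35 (0.702) without wild-type sample 1 or 3, where another probe was used.

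Signals near background limit Gli1, Mycn and Atoh1, which were not tested, Mcidas and Shh at P21, and every gene given only a lower bound. Signals near the top of the scale limit Ttr, whose group means were all 15.9 or above.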

Other observations

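The lists, genes and tests in this part were chosen only after the results were seen, with these exceptions. Cpa3 and Tpsb2 at P0 and Dct at P21 had been named by the fixed rule. Eif2s3y, Kdm5d and Xist belong to the planned list of sex-linked genes.

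Several genes listed for mast cells and pigment cells were lower in tumors, which alone does not show a loss of these cells. In wild-type CP Hdc lay at 13.06 at P0 and 13.01 at P21, while Cpa3 lay at 9.87 and 6.84. Dct was at 7.03 and 11.02 there while Pmel was at 9.01 and 7.64, so members need not share a source. Of 7 mast cell genes, 5 fell and 1 rose at P0, and 5 fell and 2 rose adjusted over the list alone (median -1.41, or -0.94 with bounded genes at their bound, camera adjusted p = 0.0255). That shift was lost with an estimated correlation (adjusted p = 0.399 with an estimated correlation) and without P0 tumor sample 2 (0.0601). The carboxypeptidase Cpa3 fell by 2.77 ± 0.36 (SE, n = 3 per group, adjusted p = 0.000411) at P0 and by 1.63 ± 0.36 (0.0068) at P21. The chymase Cma1 fell by 2.00 ± 0.37 (0.00439) at P0, and the tryptase Tpsb2 was at least 3.87-fold lower (adjusted p = 0.000317). Hdc, which makes histamine, fell by 0.74 ± 0.21 (0.0451) and Mcpt4 was at least 1.92-fold lower (adjusted p = 0.0284) at P0. Hdc failed without tumor sample 1 or 2 (0.0938, 0.094) or wild-type sample 2 or 3 (0.0744, 0.154), and Mcpt4 without tumor sample 2 or 3 (0.0651, 0.109) or wild-type sample 1 or 3 (0.0922, 0.0958). The receptor gene Kit, active in mast cells, melanocytes and other cells, instead rose by 0.90 ± 0.23 (0.0285) at P0, but not without tumor sample 2 or 3 (0.0649, 0.0816) or wild-type sample 2 or 3 (0.0658, 0.0913). Gata2 was the other one to rise adjusted over the list alone (0.69 ± 0.25).

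At P21, 4 mast cell genes fell (Cpa3, Tpsb2, Cma1 and Hdc) and 2 rose, also adjusted over the list alone, without a shift of the list (median -0.91, or -0.71 with bounds, camera adjusted p = 0.361). Kit rose by 2.68 ± 0.23 (8.51e-06), Gata2 by 1.08 ± 0.25 (0.00916), and Hdc fell by 0.91 ± 0.21 (0.0104). Tpsb2 (at least 1.43-fold lower, adjusted p = 0.017) failed without tumor sample 3 (0.0546) or wild-type sample 1 or 2 (0.0567, 0.0565), and Cma1 (at least 1.64-fold lower, adjusted p = 0.0407) without any of tumor samples 1, 2 and 3 (0.0911, 0.129, 0.0727) or wild-type samples 1, 2 and 3 (0.153, 0.0566, 0.0892). Of 5 melanocyte genes, 2 fell and none rose at each age, and 3 fell adjusted over the list alone with Tyrp1. The list medians were -0.96 and -0.90 (camera adjusted p = 0.0297 and 0.00162, and adjusted p = 0.227 and 0.0274 with an estimated correlation). The P0 shift ended without tumor sample 2 (0.0601) or wild-type sample 2 (0.0571). This list, made after the data were seen, holds Dct, one of the largest P21 falls, so its P21 shift is no independent support. The same holds for the mast cell list at P0 with Cpa3 and Tpsb2. Dct fell by 3.27 ± 0.28 (6.1e-06) at P21. At P0 it fell by 0.96 ± 0.28 (0.0424), but not without tumor sample 1, 2 or 3 (0.0734, 0.0947, 0.102) or wild-type sample 1, 2 or 3 (0.115, 0.0504, 0.0872). The melanosome gene Pmel fell by 1.14 ± 0.22 (0.00601) at P0 and by 0.90 ± 0.22 (0.0125) at P21, there not without tumor sample 1 (0.0503) or wild-type sample 3 (0.0558). No neutrophil gene passed at either age (camera adjusted p = 0.393 and 0.361).

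Genes of reactive astrocytes rose in P21 tumors. Of 10 members 8 rose and none fell, and 10 rose adjusted over the list alone (median 2.64, or 2.27 with bounded genes at their bound, camera adjusted p = 1.77e-08, and adjusted p = 0.0146 with an estimated correlation), while none passed at P0 (median -0.43, 0.397). Complement C4b rose by 4.71 ± 0.36 (2.7e-06) and the protease inhibitor gene Serpina3n by 3.66 ± 0.42 (7.44e-05) at P21. The reactive astrocyte list was also made after the data were seen. It holds C4b, one of the largest rises with age in tumors, so its P21 shift is no independent support. The list's median above the wild-type mean was 1.81, 2.99 and 2.45 in P21 tumor samples 1, 2 and 3. Ribosomal protein genes shifted up at P0 (median 0.47, camera adjusted p = 6.03e-05) and oxidative phosphorylation genes down at P21 (median -0.54, 6.51e-06), with adjusted p = 0.536 and 0.546 with an estimated correlation. None of 47 ribosomal genes passed on its own at P0, and 3 of 65 oxidative phosphorylation genes fell at P21, or 1 (Cox8b, by 1.63 ± 0.32, 0.00363) adjusted over the list alone. The other 2 were Atp5a1, which failed without tumor sample 2 or 3 (0.107, 0.0678) or wild-type sample 2 or 3 (0.102, 0.0616), and Atp5md, which failed without tumor sample 1, 2 or 3 (0.0717, 0.0703, 0.0636) or wild-type sample 1 or 2 (0.0952, 0.123).

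The Y-linked genes Eif2s3y and Kdm5d were below background in P21 tumor samples 1 and 3 and detected elsewhere. Xist, transcribed from the inactive X chromosome, was below background in P0 wild-type sample 1, P21 tumor sample 2 and P21 wild-type sample 2. In all 12 arrays both Y-linked genes were either detected or not, with Xist detected wherever they were not. Pools of different sex are a candidate explanation of the lower Y-linked signals in P21 tumors, and the sex of the pooled animals is not given in the sources used here. The pattern held in 12 of 12 arrays, but only P21 tumor samples 1 and 3, which lack Y-linked signal, bear on it. Every P21 wild-type array detected both Y-linked genes, so sex may partly go with genotype at P21.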
